A study of Nothobranchius furzeri with 20 samples.

How the data were processed

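RNA-seq of brain samples was analysed from 20 libraries of male turquoise killifish (Nothobranchius furzeri), a short-lived annual fish, of the strain MZM-04/10p. The fish had received rotenone, an inhibitor of complex I of the mitochondrial respiratory chain, at a dose given as a percentage of the LC50, the concentration lethal to a set share of animals. The labels give 4 groups of 5 libraries: 0.1%, 1% and 10% of the LC50 at 9 weeks of age, and 1% at 27 weeks. The labels do not give the length of exposure. No untreated group was analysed here. Each library has its own number in the labels, so replicate numbers here follow the order of deposition and only name a library. No label says that the libraries came from separate fish. The p-values then measure only the spread between these libraries, which may be technical in part.

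Per the labels, libraries were made from total RNA with the Illumina TruSeq RNA kit version 2, which selects poly(A) RNA and does not mark the strand. Per the submitters' processing notes, CASAVA 1.8.2, STAR 2.4.1d and featureCounts 1.4.6-p4 were used. The settings of these tools and the genome build are not given in the sources used here. The deposited count tables hold whole-number read counts per gene, not normalized, with 1 column per library. The group at 0.1% of the LC50 was deposited in a table of its own and the other 15 libraries in another. That table and its RPKM counterpart each hold 10 further columns of per-sample values that match no sample of the series, and these were not used in any step. Since raw counts carry no table-wise scaling, the 20 libraries were scaled together here, but any technical difference between the tables falls together with the 0.1% group.

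The deposited RPKM tables carry that unit in their names. Compared with the counts, the divisor for the library total repeats down the table with a period of 35 genes. The ratio of count to RPKM between a pair of libraries varied by a standard deviation of 4.3e-05 (log2) within a position of that period and by 0.202 over all positions in the table of 15 libraries, and by 4.4e-05 and 0.231 in the table of 5 libraries. The RPKM values are therefore not normalized per library. They served only as an alternative, with limma-trend on log2(RPKM + 0.1), and no level was compared between the tables in that unit.

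The tables list 26739 genes, and all 26739 are in the gene annotation deposited with the series, which supplied symbols and positions. Coordinates are 1-based, on sequences named sgr (linkage groups) and scaffold, and the annotation does not name its build. Of these genes 18287 carry a symbol and 3955 overlap another gene. Overlapping genes and symbols with a suffix such as (2 OF 2), which mark copies, are uncertain, since reads may be shared between them and strand is not marked. No entry of the tables lacked a gene identifier. Total counts ran from 20193761 to 29499193 reads per library, and 21571 to 21902 genes had at least 1 read. Within groups, the Pearson correlation of log2 counts between pairs of libraries ran from 0.9661 to 0.9891. The chi-square per degree of freedom between such pairs, over genes with a mean count of at least 20, was 7.96 to 42.11, so no pair agreed within sampling noise and each library counted as 1.

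Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with its default minimum count of 10 and minimum total of 15, which left 19556 genes (17486 with a symbol). Libraries were scaled by TMM factors, and 1 robust quasi-likelihood model with 4 group means was fitted to all 20 libraries. The comparisons were 27 against 9 weeks at 1% of the LC50, and, at 9 weeks, 10% against 1%, 1% against 0.1% and 10% against 0.1%. Each was tested with edgeR's quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p below 0.05. A dose trend on log10 dose was tested in the same way over the 15 libraries at 9 weeks, where 19389 genes passed the filter. Levels are TMM-scaled CPM, given as mean ± SD over n = 5 libraries. Fold changes are log2 values with their standard errors.

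The 31 gene lists were fixed before the data were examined, as were the comparisons, the rule for named genes and the alternatives not said to be chosen later. The lists were complex I subunits and assembly factors, other respiratory chain and ATP synthase subunits, mitochondrially encoded proteins, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, glycolysis and lactate, integrated stress response, antioxidant and NRF2 targets, heat shock and chaperones, proteasome, lysosome and autophagy, complement and acute phase, microglia, lymphocytes and granulocytes, antigen presentation and interferon response, oligodendrocyte and myelin, radial glia and astrocytes, proliferation and DNA replication, neurogenesis, neuronal and synaptic genes, monoaminergic and cholinergic neurons, neuropeptides and pituitary hormones, immediate early genes, circadian clock, xenobiotic metabolism, p53 and cell cycle arrest, vascular and meningeal cells with extracellular matrix, blood cells, retina and pineal photoreceptors, muscle, and lens crystallins. Symbols were matched without regard to case, to copy numbers or to the fish suffixes a and b. The lists hold 1054 genes, 6 of them in more than 1 list. Lists with at least 5 tested members, 30 in all, were tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The same test with the correlation estimated from the data, and fry, were alternatives.

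The named genes were chosen by rule. For each comparison they are the 8 largest rises and the 8 largest falls among called genes with a symbol, a mean log2 CPM of at least 1 and no overlap between the groups' libraries. To these come the 2 members of smallest p from each list that passed its test or held at least 3 called members. The trend names the 4 genes of smallest p in each direction. A correlation across genes compared the difference between 10% and 0.1% of the LC50 with that between 27 and 9 weeks, on mean log2 CPM with a prior count of 2. The comparisons share no library, and p came from all 252 relabellings of the 10 libraries of the age comparison.

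Alternatives were RLE and upper-quartile scaling, no low-count filter (at least 1 read), a stricter filter (CPM of at least 1 in 5 libraries), a model of only the groups compared, limma voom, DESeq2 1.42.0, limma-trend on the RPKM values, a linear dose, Spearman correlation and leaving out each library in turn. Chosen after seeing the data were an index of transcript ends as a covariate, removal of each library's trend on exon length, leaving out the 3 libraries lowest for telencephalon markers, and leaving out genes that fell over 2-fold at 27 weeks from the correlation. The index is the median, over 341 pairs of neighbouring gene models with the same symbol on the same strand, of the log2 CPM of the 5' model minus that of the 3' model, after centring each pair on its mean over the 20 libraries. The score of a marker set in a library is the median over its genes of log2 CPM centred per gene, and scores were compared with exact two-sided permutation tests.

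The gene test was checked on simulated counts with 200 changed genes among 19556. In the simulation of 27 against 9 weeks it recovered 38 of 67 genes changed 1.5-fold, 51 of 67 changed 2-fold and 61 of 66 changed 4-fold, with 9 false calls. For 10% against 1% the same counts were 35, 51 and 61, with 11 false calls. For 1% against 0.1% they were 33, 53 and 58, with 5 false calls, and for 10% against 0.1% they were 42, 53 and 63, with 10 false calls. A proteasome list raised 1.5-fold was recovered in each of the 4 comparisons, with 0 other lists called. For the correlation, 20 simulations with no shared effect gave values from -0.034 to 0.06. Each simulated gene was drawn independently, so the checks of the lists and of the correlation do not cover genes that vary together.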

Results

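Gene expression was measured by RNA-seq in the brains of male killifish that had received rotenone, at 0.1%, 1% or 10% of the LC50 in the 9-week groups and at 1% in the 27-week group, with 5 libraries in each of the 4 groups. Total counts ran from 20193761 to 23841436 reads at 0.1% of the LC50, from 20297949 to 22529663 at 1% and from 20442688 to 28290878 at 10%. In the older fish they ran from 20953093 to 29499193. The first principal component of log2 CPM held 33.6% of the variance and placed the 27-week libraries at 48.5 to 60 and the 15 libraries at 9 weeks between -37 and 7.6. The second held 9.1%.

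Several measures of the libraries differed between groups. The index of transcript ends, which is lower where the 5' gene models of a symbol lose reads relative to the 3' models, averaged 0.13 ± 0.08 (SD, n = 5) at 0.1% of the LC50, 0.07 ± 0.04 at 1%, -0.08 ± 0.11 at 10% and -0.07 ± 0.05 at 27 weeks. It was lower at 27 than at 9 weeks by an exact two-sided permutation test (difference -0.14, p = 0.00794, the smallest such a test can give). It was also lower at 10% than at 1% (difference -0.15, exact permutation p = 0.0238) and than at 0.1% (difference -0.2, exact permutation p = 0.0159), while 1% and 0.1% differed by -0.06 (exact permutation p = 0.198). A score of 20 genes that mark the telencephalon, the front of the forebrain, was higher at 27 weeks than at 9 weeks (difference 0.55, exact permutation p = 0.0397) and higher at 10% than at 1% (difference 0.64, exact permutation p = 0.0238). Markers of the hindbrain and spinal cord differed by 0.62 between 10% and 1% (exact permutation p = 0.206, with 21 of 23 genes positive and a median of 0.38). Pituitary hormone genes varied strongly within groups: prolactin (PRL) averaged 213 ± 182 CPM at 10% of the LC50, 47.2 ± 64.8 at 1%, 1.09 ± 1.13 at 0.1% and 105 ± 103 at 27 weeks (SD, n = 5).

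The comparison of 27 with 9 weeks at 1% of the LC50 asked how the brain differed between the ages at the same dose. The labels do not say how long the fish had received rotenone, so age and length of exposure may differ together. Some genes of dividing cells were lower in the older fish. MKI67, a nuclear protein of cycling cells (sgr12, 34892255 to 34901973, + strand), averaged 18.7 ± 10.7 CPM (SD, n = 5) at 9 weeks and 2.84 ± 0.611 at 27 weeks, a log2 fold change of -2.72 ± 0.39 (SE, adjusted p = 2.8e-05). KIF11, a motor protein of the mitotic spindle, changed by -2.15 ± 0.34 (adjusted p = 7.1e-05). Among genes of the cytosolic ribosome RPS6 (sgr02, 85821023 to 85841015, - strand, overlapping another gene) went from 1050 ± 76.1 to 1500 ± 62.8 CPM, a log2 fold change of 0.52 ± 0.06 (adjusted p = 6.04e-07). The lists of proliferation genes and of cytosolic ribosomal proteins passed at the preset correlation but not at an estimated correlation (adjusted p = 0.906 and 0.762). In MKI67, KIF11 and RPS6 all 5 older libraries lay outside the range of the 5 younger ones.

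With edgeR's quasi-likelihood test, 5753 of 19556 genes were called between 27 and 9 weeks, 2760 higher and 2993 lower. Of the called genes 1102 differed over 2-fold, 157 higher and 945 lower, and 156 were over 8-fold lower against 1 higher. The groups did not overlap in 21.25% of genes, where chance gives 0.79%. RLE scaling gave 2369 higher and 3143 lower, and upper-quartile scaling 3135 and 2877, so which direction held more calls rests on the scaling. Removing each library's trend on exon length, an alternative chosen after seeing the data, moved the split to 4132 higher and 2336 lower.

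Under the rule for named genes the largest falls were as follows. LINGO3, a leucine-rich repeat membrane protein (sgr09, 43439641 to 43442278, - strand), averaged 24.4 ± 6.19 CPM at 9 weeks and 0.295 ± 0.0704 at 27 weeks, a log2 fold change of -6.33 ± 0.37 (adjusted p = 2.07e-10). MGAT3, a glycosyltransferase of N-glycans (sgr02, 81475679 to 81487296, + strand), fell from 43.8 ± 16.8 to 0.596 ± 0.178 CPM (log2 fold change -6.22 ± 0.42, adjusted p = 1.74e-09). RYR3 (2 OF 2), a calcium release channel, changed by -6.14, ANKRD52A, a regulatory subunit of a protein phosphatase, by -6.08, DMXL1 by -5.87, the septin SEPT5B by -5.83, ZC3H12B by -5.51 and CU855953.1 by -5.38, with adjusted p from 2.81e-11 to 1.56e-05. All 5 older libraries were below all 5 younger ones for each of these 8 genes. ANKRD52A and DMXL1 each have a further gene model of the same symbol on the 3' side, which changed less, by -2.25 and -1.9. For these symbols the value above is that of the 5' model only. With a mean log2 CPM of at least 1 there were 105 genes that fell over 8-fold, with a median log2 fold change of -3.67, and 4 of them overlap another gene. The median of these 105 genes per library, relative to the mean at 0.1% of the LC50, was between -3.89 and -3.43 in the 27-week libraries, between -1.45 and -0.59 at 10%, between -0.57 and 0.2 at 1% and between -0.36 and 0.31 at 0.1%. The index of transcript ends was lower in the older fish as well, and with it as a covariate, chosen after seeing the data, 3623 genes were called.

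**Figure D1:**
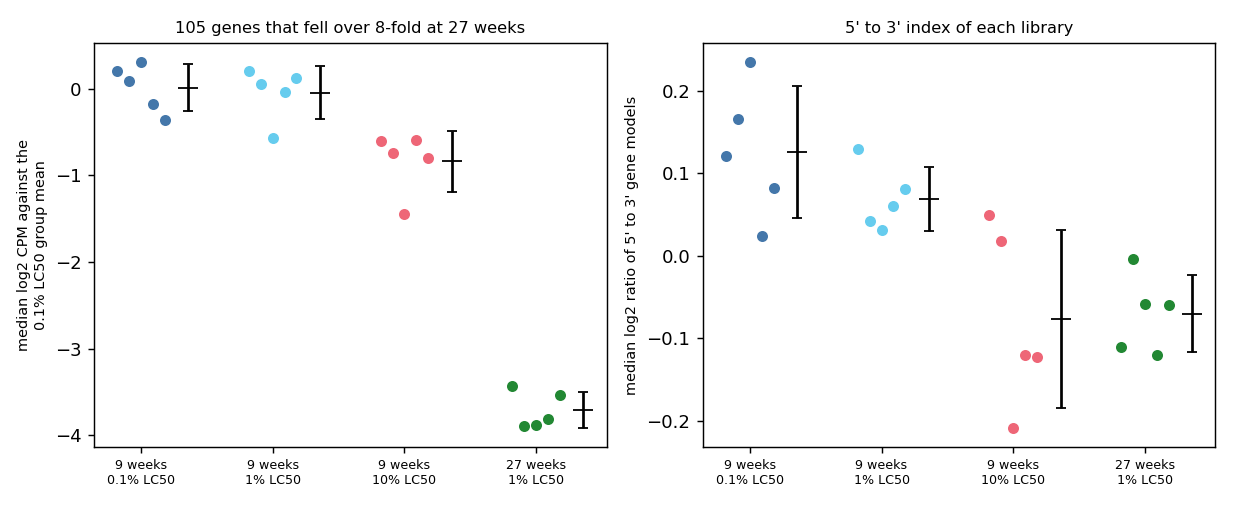
Median log2 CPM, relative to the mean at 0.1% of the LC50, of the 105 genes that fell over 8-fold at 27 weeks, and the index of transcript ends (log2, 5' minus 3' gene models), for each of the 20 libraries in the 4 groups, with each point 1 library. The 27-week libraries lie between -3.89 and -3.43 and the libraries at 10% between -1.45 and -0.59, while the index is -0.08 ± 0.11 (SD, n = 5) at 10% and -0.07 ± 0.05 at 27 weeks.

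Under the same rule the largest rises at 27 weeks were smaller. DIABLO (2 OF 2), a mitochondrial protein released in apoptosis (sgr06, 6363378 to 6365673, + strand), averaged 1.86 ± 0.949 CPM at 9 weeks and 7.1 ± 3.2 at 27 weeks (log2 fold change 1.92 ± 0.51, adjusted p = 0.00821). The T-box transcription factors TBX16, TBR1B and EOMESA rose by 1.88, 1.86 and 1.77. TBR1B (sgr14, 30487487 to 30491735, - strand) and EOMESA (sgr19, 9744221 to 9748930, + strand) mark excitatory neurons of the telencephalon, whose marker score was also higher at 27 weeks, and their standard errors of 0.66 and 0.64 gave adjusted p of 0.0411 and 0.046. Both stayed called without replicate 1 or 2 of the 9-week group. The calls ended without replicate 3, 4 or 5 of the 9-week group or any 27-week library (adjusted p from 0.0551 to 0.106). Without replicate 3 EOMESA was at 1.5 and TBR1B at 1.59, and without replicate 5 they were at 1.47 and 1.54. Leaving out the 3 libraries lowest for telencephalon markers, which include both, left 1.1 and 1.18 (adjusted p = 0.0405 and 0.0333). TMEM176 rose by 1.78, the cannabinoid receptor CNR1 (2 OF 2) by 1.77, the carbonic anhydrase CA6 (2 OF 2) by 1.71 and CR388068.1 by 1.61, with adjusted p from 5.83e-05 to 0.019. CA6 (2 OF 2) overlaps another gene. Replicates 3 and 5 of the 9-week group were also the lowest for TBX16 (0.805 and 0.961 CPM against 2.28 to 3.92 in the others). The same held for CNR1 (2 OF 2) (5.72 and 5.45 against 9.37 to 33.3) and CR388068.1 (3.58 and 4.9 against 6.46 to 10.5). In DIABLO (2 OF 2), TMEM176 and CA6 (2 OF 2) these replicates were not the lowest pair. For all of these 8 genes the 5 older libraries were above the 5 younger ones.

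Of 30 lists tested, 7 passed the list test between 27 and 9 weeks, 5 up and 2 down, and with an estimated correlation 0 passed in camera (1 at an unadjusted p below 0.05, against 11 passing in fry). At 27 weeks the index of transcript ends was lower, and with it as a covariate 3 of the 7 still passed, those of cytosolic ribosomal proteins, proliferation genes and neuronal genes. The count was 11 without replicate 2 or 4 of the 9-week group and 15 without replicate 2 of the 27-week group. Cytosolic ribosomal proteins rose as a list (median log2 fold change 0.36, adjusted p = 9.08e-28), with 68 of 69 members higher over all genes and 68 adjusted over the list alone. Proliferation and DNA replication genes fell (median -0.81, adjusted p = 1.8e-05), with 30 of 50 members lower and 1 higher, or 31 lower and 2 higher adjusted over the list alone. These calls ended with an estimated correlation (adjusted p = 0.762 and adjusted p = 0.906 with an estimated correlation). Neuronal and synaptic genes fell (median -0.29, adjusted p = 4.52e-10, and adjusted p = 0.289 with an estimated correlation). In this list 28 of 60 were lower and 6 higher, or 31 and 7 adjusted over the list alone. Among them GRIN1B, the obligatory subunit of NMDA receptors (sgr11, 4038548 to 4085418, + strand), changed by -1.21 ± 0.07 (adjusted p = 7.13e-11), from 679 ± 54.6 to 294 ± 15.3 CPM. Beside this list the lower index of transcript ends at 27 weeks stands as a measured difference.

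Heat shock and chaperone genes rose at 27 weeks (median 0.17, adjusted p = 0.0344, and adjusted p = 0.762 with an estimated correlation). In this list 8 of 25 were higher and 0 lower, also 8 adjusted over the list alone. The co-chaperone BAG3 changed by 0.44 ± 0.07 (adjusted p = 5.7e-05) and HSPA8 by 0.7 ± 0.17 (adjusted p = 0.00324). This HSPA8 gene model had a low level, 2.01 to 3.98 CPM per library at 9 weeks and 4.41 to 5.17 at 27 weeks. Lysosome and autophagy genes rose (median 0.19, adjusted p = 0.0185, and adjusted p = 0.906 with an estimated correlation). In this list 10 of 44 were higher and 2 lower, or 7 and 2 adjusted over the list alone. GABARAPA and MAP1LC3B, proteins of the autophagosome membrane, both changed by 0.36 ± 0.05 (adjusted p = 2.44e-05 and 1.39e-05). Microglia and macrophage markers rose (median 0.46, adjusted p = 0.0371, and adjusted p = 0.977 with an estimated correlation). In this list 5 of 25 were higher, or 2 adjusted over the list alone. Among them CORO1A, an actin-binding protein of leukocytes, changed by 0.77 ± 0.2 and the apolipoprotein APOEB by 0.66 ± 0.2 (adjusted p = 0.00523 and 0.0165). In both genes the 27-week libraries overlapped those at 0.1% of the LC50. Mitochondrial ribosomal proteins rose (median 0.09, adjusted p = 0.0371, and adjusted p = 0.977 with an estimated correlation). In this list 13 of 62 were higher, or 12 adjusted over the list alone, including MRPL45 (0.47 ± 0.1) and MRPS9 (0.31 ± 0.05). The 27-week libraries overlapped those at 0.1% of the LC50 in MRPL45 but not in MRPS9. With the index of transcript ends as a covariate none of these 4 lists passed. The medians were then 0.13 for heat shock genes, 0.14 for lysosome genes and 0.31 for microglia markers (adjusted p = 0.11 in each), and 0.03 for mitochondrial ribosomal proteins (adjusted p = 0.509).

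Several lists held called genes at 27 weeks without passing their own test. In complement and acute phase 6 of 21 genes were higher and 1 lower (median 0.77, adjusted p = 0.061), or 10 and 2 adjusted over the list alone. There C1QA, a component of the first complement complex, changed by 0.99 ± 0.23 (adjusted p = 0.00271) and ceruloplasmin, CP, by -0.58 ± 0.16 (adjusted p = 0.0113). Of 25 oligodendrocyte and myelin genes 11 were lower and 1 higher (median -0.37, adjusted p = 0.061), or 13 and 1 adjusted over the list alone. Among them the precursor cell genes GPR17 and PDGFRA changed by -0.92 ± 0.19 and -0.49 ± 0.12 (adjusted p = 0.00075 and 0.00394). In p53 and cell cycle arrest 8 of 25 genes were higher and 0 lower (median 0.19, adjusted p = 0.0725), or 9 higher adjusted over the list alone. There CCNG1 was at 0.54 ± 0.1 and GADD45AB at 1.05 ± 0.26 (adjusted p = 0.000387 and 0.00479). The 27-week libraries overlapped those at 0.1% of the LC50 in GADD45AB but not in CCNG1. Complex I, the target of rotenone, had 8 of 33 genes higher (median 0.09, adjusted p = 0.061), or 4 adjusted over the list alone. Among them NDUFS1 was at 0.22 ± 0.05 (adjusted p = 0.000989) and the assembly factor NDUFAF2 at 0.28 ± 0.09 (adjusted p = 0.0177). Neuropeptides had 7 of 26 genes higher (median 0.35, adjusted p = 0.061), also 7 adjusted over the list alone. There TAC1, the precursor of substance P, was at 1.14 ± 0.18 (adjusted p = 8.21e-05) and ADCYAP1B, the precursor of PACAP, at 0.44 ± 0.09 (adjusted p = 0.000697). In neurogenesis 13 of 41 genes were lower and 5 higher (median -0.11, adjusted p = 0.463), or 14 and 5 adjusted over the list alone. There NEUROD4 was at -1.06 ± 0.16 and SOX11A at -0.8 ± 0.11 (adjusted p = 3.18e-05 and 1.29e-05). Of 31 circadian clock genes 8 were higher and 4 lower (median 0.1, adjusted p = 0.77), or 9 and 4 adjusted over the list alone. The nuclear receptor RORAA (sgr13, 22474324 to 22554572, - strand) changed by -3.01 ± 0.13 (adjusted p = 4.09e-12) and DBPA by -0.6 ± 0.12 (adjusted p = 0.000507).

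**Figure D2:**
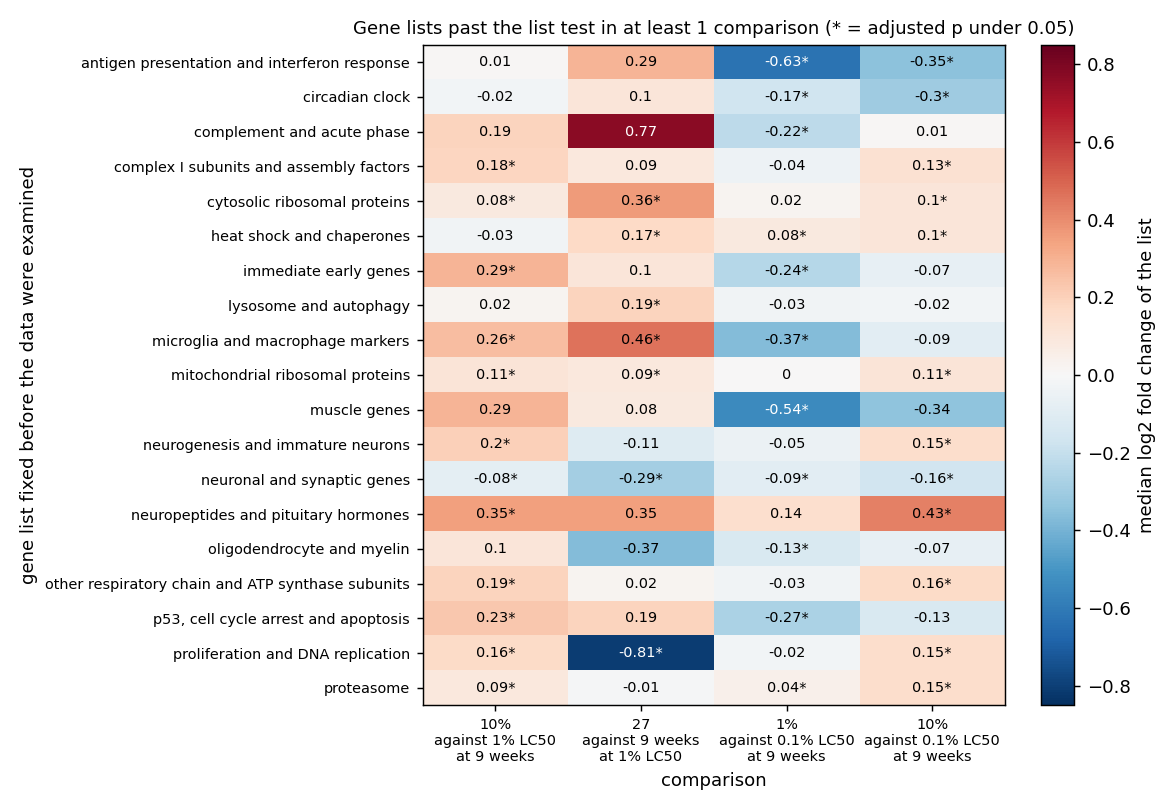
Median log2 fold change of the members of each gene list (one line per list) in the 4 pairwise comparisons (columns), with colour and printed value giving the median and a star marking lists past the list test at the preset correlation. Cytosolic ribosomal proteins stand at 0.36 and proliferation genes at -0.81 between 27 and 9 weeks.

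The comparison of 10% with 1% of the LC50 at 9 weeks asked what a higher dose changed at the same age. Some genes of the respiratory chain were slightly higher at 10%. NDUFA12 (sgr01, 94296519 to 94299155, - strand) and NDUFB7 (scaffold00339, 117042 to 118535, + strand), subunits of complex I, changed by 0.24 ± 0.06 and 0.2 ± 0.05 (SE, adjusted p = 0.0251 and 0.0262), NDUFB7 from 41.5 ± 1.68 to 47.7 ± 3.13 CPM (SD, n = 5). The complex IV subunit COX6B1 changed by 0.48 ± 0.1 and ATP5O, a subunit of ATP synthase, by 0.31 ± 0.07 (adjusted p = 0.0147 and 0.0189). The index of transcript ends was lower at 10% too, and with it as a covariate NDUFA12, NDUFB7, COX6B1 and ATP5O stood at 0.17, 0.15, 0.5 and 0.34 and were not called (adjusted p from 0.177 to 0.363). Among synaptic genes GRIN1B was lower: it changed by -0.53 ± 0.07 (adjusted p = 0.00338), from 679 ± 54.6 to 472 ± 34 CPM. In each of these genes all 5 libraries at 10% lay outside the range of the 5 at 1%.

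Under the rule for named genes, which leaves out larger changes in genes of low level or with overlapping groups, the largest rises at 10% were CPA1, a digestive carboxypeptidase (scaffold00835, 51649 to 57136, - strand), at a log2 fold change of 1.29 ± 0.35 (adjusted p = 0.0368), the transcription factor KLF11B (sgr16, 30684767 to 30689552, - strand) at 1.21 ± 0.26 (adjusted p = 0.0169) and the immediate early gene FOSB (sgr06, 21924879 to 21932878, + strand) at 1.19 ± 0.25 (adjusted p = 0.0147), which went from 26 ± 9.99 to 59.2 ± 12.8 CPM. Other large rises were CHP2 at 1, CPB1, another carboxypeptidase, at 0.96, TSC22D2 (2 OF 2) at 0.94 and GBP at 0.91, with adjusted p from 0.00949 to 0.0495. The largest falls under the rule were MLL3 (2 OF 2), a histone methyltransferase (scaffold03490, 92 to 5071, + strand), at -1.42 ± 0.32 (adjusted p = 0.0181), SYNE2A, a nuclear envelope protein, at -1.17, the growth factor FGF8A at -1.05, the melatonin receptor MTNR1B at -1.03, MLL4B at -1, FAM135B at -0.98, the kinesin KIF13A at -0.94 and CACNG3B, an auxiliary subunit of AMPA receptors, at -0.94, with adjusted p from 0.00764 to 0.0423. The value of MLL4B is that of a 5' gene model only. At 10% against 0.1% this model was at -0.89 and the 3' model of the same symbol at 0.06. Of the 105 genes that fell over 8-fold at 27 weeks, all 105 had a negative value at 10% against 1% (median -0.79), and 69 were called lower. Both comparisons use the 1% libraries at 9 weeks, so this is in part built in by the choice of the genes.

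Of 30 lists, 12 passed the test at 10% against 1%, 11 up and 1 down, and with an estimated correlation 0 passed in camera (3 at an unadjusted p below 0.05, against 6 passing in fry). Complex I genes rose (median 0.18, adjusted p = 1.59e-10, and adjusted p = 0.388 with an estimated correlation). In this list 8 of 33 were called higher, or 22 adjusted over the list alone, and all 33 had positive values. Other respiratory chain genes rose (median 0.19, adjusted p = 1.06e-10, and adjusted p = 0.388 with an estimated correlation). In this list 5 of 29 were higher, or 18 adjusted over the list alone. With the index of transcript ends as a covariate 6 lists passed, and the medians of these were 0.11 for complex I (adjusted p = 0.000395) and 0.14 for the other respiratory chain genes (adjusted p = 3.47e-06). Mitochondrial ribosomal proteins (median 0.11, adjusted p = 2.76e-05, and adjusted p = 0.538 with an estimated correlation) had 3 of 62 higher, also 3 adjusted over the list alone. Among them MRPL45 was at 0.54 ± 0.1 and MRPL43 at 0.31 ± 0.08 (adjusted p = 0.0118 and 0.0333). Cytosolic ribosomal proteins (median 0.08, adjusted p = 6.55e-05, and adjusted p = 0.757 with an estimated correlation) had 0 of 69 called, and their median was -0.02 with the index of transcript ends as a covariate. Proteasome genes (median 0.09, adjusted p = 0.00303, and adjusted p = 0.757 with an estimated correlation) had 2 of 40 higher, also 2 adjusted over the list alone: PSMA2 at 0.22 ± 0.06 and PSMB2 at 0.21 ± 0.06 (adjusted p = 0.0473 and 0.0429).

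Neuronal and synaptic genes were the list that fell at 10% against 1% (median -0.08, adjusted p = 0.000772, and adjusted p = 0.538 with an estimated correlation). In this list 7 of 60 were lower and 1 higher, or 15 and 1 adjusted over the list alone. The index of transcript ends was lower in the same comparison (difference -0.15, exact permutation p = 0.0238), and with it as a covariate the median of this list was -0.02 (adjusted p = 0.386). Neurogenesis genes rose (median 0.2, adjusted p = 7.46e-06, and adjusted p = 0.388 with an estimated correlation). In this list 3 of 41 were higher, or 12 higher and 1 lower adjusted over the list alone, and here the telencephalon score was higher as well. DPYSL5B, a protein of growing axons, changed by 0.3 ± 0.08 and HMGB1B by 0.21 ± 0.05 (adjusted p = 0.0315 and 0.032). Immediate early genes rose (median 0.29, adjusted p = 7.39e-05, and adjusted p = 0.538 with an estimated correlation). In this list 3 of 31 were higher, also 3 adjusted over the list alone, including FOSB and the nuclear receptor NR4A3 at 0.85 ± 0.13 (adjusted p = 0.00635). The p53 list rose (median 0.23, adjusted p = 0.00676, and adjusted p = 0.388 with an estimated correlation). In this list 4 of 25 were higher, or 6 adjusted over the list alone. Among them GADD45AA, a stress-induced growth arrest gene, was at 0.45 ± 0.08 and CASP3A, an executioner caspase, at 0.33 ± 0.07 (adjusted p = 0.0104 and 0.0126). Neuropeptides and pituitary hormones rose (median 0.35, adjusted p = 0.00342, and adjusted p = 0.516 with an estimated correlation). In this list 4 of 26 were higher, or 5 adjusted over the list alone. Among them TAC1 was at 0.86 ± 0.18 and ADCYAP1B at 0.43 ± 0.09 (adjusted p = 0.0153 and 0.0134). Microglia markers (median 0.26, adjusted p = 0.02, and adjusted p = 0.757 with an estimated correlation) had 2 of 25 higher, also 2 adjusted over the list alone, CORO1A at 0.7 ± 0.2 and the integrin ITGB2 at 0.29 ± 0.07 (adjusted p = 0.0434 and 0.0325). Proliferation genes passed with a median of 0.16 (adjusted p = 0.0134, and adjusted p = 0.757 with an estimated correlation) and 0 of 50 members called. The p53, immediate early and microglia lists did not pass at 10% against 0.1% (medians -0.13, -0.07 and -0.09, adjusted p = 0.173, 0.605 and 0.909). All 3 had fallen at 1% against 0.1%, so their rises here set them apart from the 1% group only. The other lists that passed here also passed at 10% against 0.1%, in the same direction. In GADD45AA, CASP3A, NR4A3, CORO1A and ITGB2 the libraries at 10% overlapped those at 0.1%.

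With edgeR's quasi-likelihood test, 1093 genes were called between 10% and 1%, 425 higher and 668 lower, of which 107 differed over 2-fold, and 5.47% of genes had groups without overlap where chance gives 0.79%. The call count was 596 and 652 without replicates 4 and 5 of the 1% group, and 1841, 175, 614 and 329 without replicates 1, 3, 4 and 5 of the 10% group. With the index of transcript ends as a covariate 1 gene was called (2241 at an unadjusted p below 0.05), a model of these 2 groups alone called 183, DESeq2 called 1901, and leaving out the 3 libraries lowest for telencephalon markers left 571.

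The comparison of 1% with 0.1% of the LC50 asked what changed between the lower doses, with the 0.1% group taken from a separate table. Several genes of the output arm of the circadian clock were lower at 1%. C19H1ORF51 (1 OF 2), a repressor of the clock (sgr19, 10434437 to 10442562, + strand), averaged 80.6 ± 44.6 CPM (SD, n = 5) at 0.1% and 14.4 ± 3.6 at 1%, a log2 fold change of -2.48 ± 0.33 (SE, adjusted p = 0.00266). The nuclear receptors NR1D4B, NR1D1 (scaffold00335, 91087 to 101445, - strand) and NR1D4A, which repress clock activators, changed by -1.92 ± 0.33, -1.44 ± 0.26 and -1.39 ± 0.21 (adjusted p = 0.00717, 0.00902 and 0.0047), and the transcription factor DBPB by -1.4 ± 0.21 (adjusted p = 0.00456). In these genes all 5 libraries at 1% were below all 5 at 0.1%.

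Other large falls under the rule for named genes were HSD11B2, an enzyme that inactivates cortisol, at -2.03 ± 0.44 (adjusted p = 0.0317), CDKN1A, an inhibitor of the cell cycle (sgr10, 48800989 to 48801714, + strand), at -1.65 ± 0.35 (adjusted p = 0.0253), BX465203.1 at -1.58, KLF11B at -1.52 ± 0.26 (adjusted p = 0.00717) and the insulin receptor substrate IRS2 at -1.5 ± 0.34 (adjusted p = 0.0368). KLF11B and FOSB, which fell by 1.4 here, are among the largest rises at 10% against 1%, a comparison that shares the 1% libraries. FOSB stood at 68.5 ± 6.34 CPM at 0.1%, 26 ± 9.99 at 1% and 59.2 ± 12.8 at 10%. The largest rises under the rule were the homeobox gene MSXB at 1.42 ± 0.21 (adjusted p = 0.00456), SERPINH1B, a collagen chaperone (sgr06, 41048406 to 41123715, - strand), at 1.23 ± 0.21 (adjusted p = 0.00726), LRIG3 at 1.09, the deubiquitinase USP21 at 1.04, CR538726.1 at 0.96, TP53RK at 0.74, PPP1R10 at 0.64 and the matrix protein FBLN1 at 0.6, with adjusted p from 0.00266 to 0.0421. TP53RK and PPP1R10 overlap other genes.

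Of 30 lists, 11 passed the test at 1% against 0.1%, 2 up and 9 down, and the p53 list alone also passed with an estimated correlation. In the p53 list (median -0.27, adjusted p = 5.93e-08, and adjusted p = 0.00642 with an estimated correlation) 5 of 25 genes were lower, or 10 adjusted over the list alone, including CDKN1A and the related inhibitor CDKN1BA at -0.91 ± 0.19 (adjusted p = 0.0215). CDKN1A stood at 29, 18.7 and 17.9 CPM in replicates 1, 4 and 5 of the 0.1% group and at 6.5 and 7.93 in replicates 2 and 3. The same replicates 1, 4 and 5 had the higher scores of the clock output arm (0.77, 0.43 and 0.64 against 0.18 and 0.06). Circadian clock genes fell (median -0.17, adjusted p = 5.74e-07, and adjusted p = 0.354 with an estimated correlation). In this list 7 of 31 were lower and 1 higher, or 10 and 2 adjusted over the list alone. Immediate early genes fell (median -0.24, adjusted p = 1.44e-08, and adjusted p = 0.354 with an estimated correlation). In this list 5 of 31 were lower, or 8 adjusted over the list alone. Among them NR4A3 was at -1.12 ± 0.13 (adjusted p = 0.00115). Heat shock genes rose (median 0.08, adjusted p = 0.000162, and adjusted p = 0.148 with an estimated correlation). In this list 2 of 25 were higher, or 7 adjusted over the list alone: SERPINH1B and the co-chaperone DNAJB1B at 0.36 ± 0.08 (adjusted p = 0.0319). Oligodendrocyte genes fell (median -0.13, adjusted p = 0.000836, and adjusted p = 0.354 with an estimated correlation). In this list 1 of 25 was lower, or 2 adjusted over the list alone, GAL3ST1, which makes the myelin lipid sulfatide, at -0.69 ± 0.16 (adjusted p = 0.0453).

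The remaining lists past the test at 1% against 0.1% held 0 called members over all genes. These were muscle genes (median -0.54, adjusted p = 0.000274), antigen presentation and interferon response (median -0.63, adjusted p = 0.00539), microglia markers (median -0.37, adjusted p = 0.00699), complement and acute phase (median -0.22, adjusted p = 0.023) and proteasome genes (median 0.04, adjusted p = 0.0462), all with adjusted p = 0.889 with an estimated correlation. Neuronal and synaptic genes had a median of -0.09 (adjusted p = 0.000624, and adjusted p = 0.553 with an estimated correlation). Without replicate 4 of the 0.1% group the microglia median was 0.03. Adjusted over the list alone, 1 proteasome gene was higher and 0 members of the other 5 lists were called.

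With edgeR's quasi-likelihood test, 233 genes were called between 1% and 0.1%, 121 higher and 112 lower, with 45 over 2-fold, and 2.71% of genes had groups without overlap where chance gives 0.79%. The count was 66, 133 and 95 without replicates 1, 4 and 5 of the 0.1% group, and 154, 86, 356, 146 and 126 without replicates 1 to 5 of the 1% group. It was 17 in a model of these 2 groups alone, 554 with DESeq2 and 46 without the 3 libraries lowest for telencephalon markers.

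**Figure D3:**
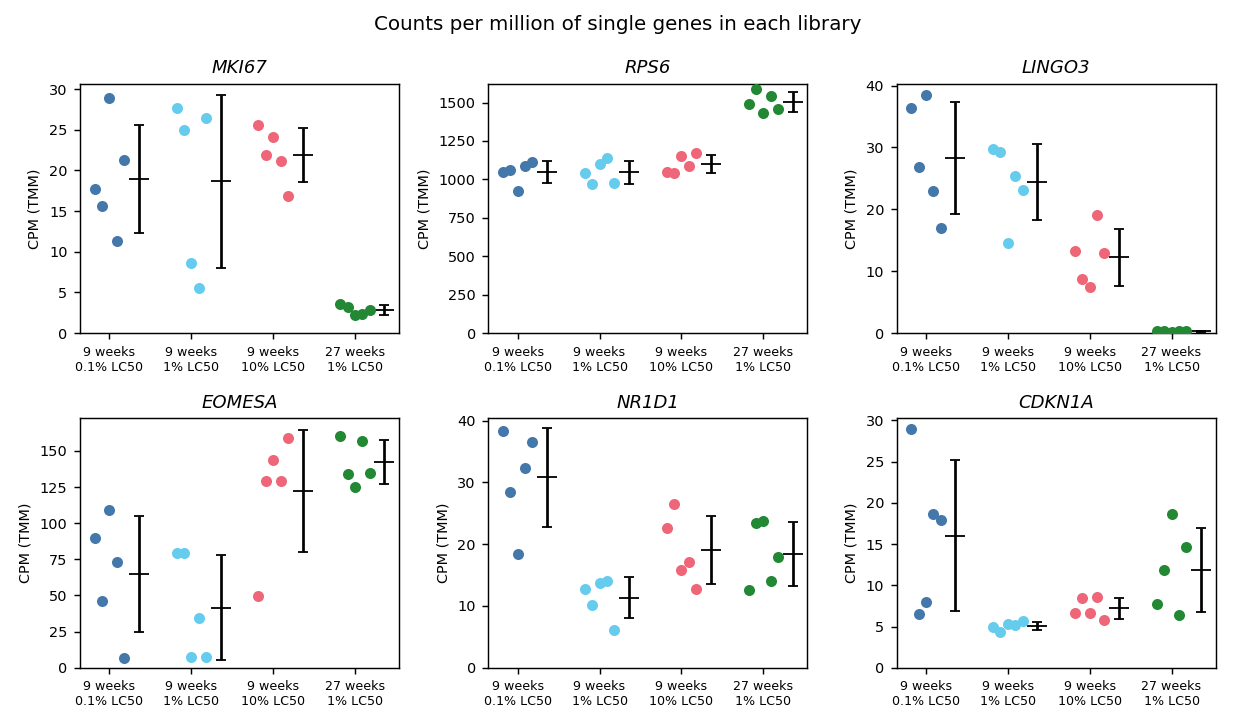
CPM of MKI67, RPS6, LINGO3, EOMESA, NR1D1 and CDKN1A in each library of the 4 groups, with each point 1 library and bars giving the mean ± SD (n = 5). NR1D1 stands at 30.8 ± 7.95 CPM at 0.1% of the LC50 and 11.3 ± 3.31 at 1%, and LINGO3 at 24.4 ± 6.19 at 1% and 9 weeks and 0.295 ± 0.0704 at 27 weeks.

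The comparison of 10% with 0.1% of the LC50 spans the widest dose range at 9 weeks. Some genes of synapses and glia were lower at 10%: GRIN1B changed by -0.48 ± 0.07 (SE, adjusted p = 0.00329), the synaptic adhesion protein NLGN2A by -0.38 ± 0.07 (adjusted p = 0.00681), the astroglial glutamate transporter SLC1A2B (sgr13, 31674678 to 31692975, - strand) by -0.5 ± 0.1 (adjusted p = 0.0109), from 1130 ± 112 to 798 ± 129 CPM (SD, n = 5), and the gap junction protein CX43 by -0.46 ± 0.09 (adjusted p = 0.0109). The list of radial glia and astrocyte markers did not pass here (median -0.01, adjusted p = 0.575), with 1 of 21 higher and 2 lower. RORAA fell from 70 ± 6.32 to 40.9 ± 8.27 CPM (log2 fold change -0.78 ± 0.12, adjusted p = 0.00517). The largest falls under the rule for named genes were C19H1ORF51 (1 OF 2) at -1.76 ± 0.31 (adjusted p = 0.00866), EPM2A, a glycogen phosphatase, at -1.75, MLL3 (2 OF 2) at -1.61, ANKRD52A at -1.35, LRRC3B at -1.35, CR678040.1 at -1.3, MGAT3 at -1.3 and LTBP1, a binding protein of TGF-beta, at -1.24, with adjusted p from 0.0107 to 0.0386 for the last 7. The value of ANKRD52A is that of its 5' gene model, and the 3' model of the same symbol was at -0.67. Of the 105 genes that fell over 8-fold at 27 weeks, all 105 had a negative value (median -0.85) and 71 were called lower, in a comparison that shares no library with that of 27 and 9 weeks.

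Of the genes called over 8-fold apart at 10% against 0.1%, 4 were higher and 2 lower, PRL among them, and all had a low level or groups that overlap. Under the rule for named genes the rises were smaller than the falls. CU457778.1 was at 0.77 ± 0.22 (adjusted p = 0.0484), HER6, a repressor of neuronal differentiation (sgr17, 19461665 to 19463957, - strand), at 0.75 ± 0.2 (adjusted p = 0.0352), METTL21D at 0.74, CCDC43 at 0.7, CU463855.1 at 0.62, the myosin MYO6B at 0.62 and MARCH5L at 0.59, with adjusted p from 0.0131 to 0.0432 for the last 5. CCDC43 overlaps another gene. PRL (scaffold00323, 115250 to 117448, + strand, overlapping another gene) differed by 7.58 ± 2.07 (adjusted p = 0.0429), with its wide spread within groups given above.

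Of 30 lists, 12 passed the test at 10% against 0.1%, 9 up and 3 down, and with an estimated correlation 0 passed in camera (3 at an unadjusted p below 0.05, against 9 passing in fry). Neuronal and synaptic genes fell (median -0.16, adjusted p = 1.61e-10, and adjusted p = 0.229 with an estimated correlation). In this list 14 of 60 were lower, or 26 lower and 1 higher adjusted over the list alone. The index of transcript ends was lower here too, and with it as a covariate the median of this list was -0.05 (adjusted p = 0.0158) and that of complex I 0.03 (adjusted p = 0.488). Circadian clock genes fell (median -0.3, adjusted p = 1.16e-06, and adjusted p = 0.385 with an estimated correlation). In this list 5 of 31 were lower, or 15 adjusted over the list alone. Among them NR1D4A was at -1.08 ± 0.21 (adjusted p = 0.0106). Antigen presentation genes passed with a median of -0.35 (adjusted p = 0.0437, and adjusted p = 0.781 with an estimated correlation) and 0 of 21 called. Proteasome genes rose (median 0.15, adjusted p = 6.04e-07, and adjusted p = 0.521 with an estimated correlation). In this list 6 of 40 were higher, or 17 adjusted over the list alone. Among them PSMA1 was at 0.2 ± 0.05 and PSME3 at 0.28 ± 0.08 (adjusted p = 0.0294 and 0.0356). Complex I genes rose (median 0.13, adjusted p = 3.38e-07, and adjusted p = 0.41 with an estimated correlation), with NDUFS6 at 0.26 ± 0.06 (adjusted p = 0.0251) the 1 called of 33, or 8 adjusted over the list alone, and all 33 had positive values. Other respiratory chain genes (median 0.16, adjusted p = 1.83e-07, and adjusted p = 0.41 with an estimated correlation) had 0 of 29 called over all genes and 16 higher adjusted over the list alone.

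Cytosolic ribosomal proteins at 10% against 0.1% had a median of 0.1 (adjusted p = 4.42e-08, and adjusted p = 0.781 with an estimated correlation) and 1 of 69 higher, RPL9 at 0.19 ± 0.05 (adjusted p = 0.045), or 0 adjusted over the list alone, and with the index of transcript ends as a covariate the median was -0.04. Mitochondrial ribosomal proteins (median 0.11, adjusted p = 8.99e-07, and adjusted p = 0.41 with an estimated correlation) had 2 of 62 higher, also 2 adjusted over the list alone, MRPL52 at 0.34 ± 0.08 and MRPL44 at 0.28 ± 0.07 (adjusted p = 0.017 and 0.0288). Neurogenesis genes rose (median 0.15, adjusted p = 0.000173, and adjusted p = 0.388 with an estimated correlation), with SOX3 higher at 0.44 ± 0.11 and ELAVL4 lower at -0.51 ± 0.11 (adjusted p = 0.0238 and 0.0141), or 7 higher and 1 lower adjusted over the list alone. The telencephalon score was higher here as well (difference 0.53, exact permutation p = 0.0397). Neuropeptides and pituitary hormones (median 0.43, adjusted p = 0.000169, and adjusted p = 0.385 with an estimated correlation) had 1 of 26 higher, PRL, or 0 adjusted over the list alone. Heat shock genes (median 0.1, adjusted p = 0.00456, and adjusted p = 0.385 with an estimated correlation) had 1 of 25 higher, DNAJB1B at 0.38 ± 0.08 (adjusted p = 0.0152), or 5 adjusted over the list alone. Proliferation genes passed with a median of 0.15 (adjusted p = 0.0258, and adjusted p = 0.781 with an estimated correlation) and 0 of 50 called.

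With edgeR's quasi-likelihood test, 1087 genes were called between 10% and 0.1%, 344 higher and 743 lower, with 68 over 2-fold, and upper-quartile scaling gave 561 higher and 662 lower. The count was 397, 474, 475 and 1816 without replicates 1, 2, 3 and 4 of the 0.1% group, and 1818, 209, 616 and 255 without replicates 1, 3, 4 and 5 of the 10% group. With the index of transcript ends as a covariate 3 genes were called (1842 at an unadjusted p below 0.05), a model of these 2 groups alone called 281, and DESeq2 called 1826.

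Across the 3 doses at 9 weeks, 223 of 19389 genes had a slope on log10 dose past the threshold in edgeR's quasi-likelihood test, 42 rising and 181 falling. The 4 rising genes of smallest p were NFE2, a transcription factor, at 0.19 ± 0.03 log2 per 10-fold dose, CIZ1A at 0.13 ± 0.02, the sulfotransferase GAL3ST4 at 0.2 ± 0.04 and LRRC61 at 0.26 ± 0.05. NFE2 averaged 177 ± 12.6 CPM at 0.1%, 214 ± 13.2 at 1% and 231 ± 11 at 10% (SD, n = 5). The 4 falling genes were the phosphate transporter SLC20A2 at -0.28 ± 0.04, the zinc finger genes ZNF704 at -0.46 ± 0.08 and ZNF804A at -0.18 ± 0.03, and the autophagy kinase ULK2 at -0.21 ± 0.04, and the adjusted p of all 8 was 0.0316. SLC20A2 averaged 262 ± 15.2, 221 ± 25.2 and 179 ± 21.3 CPM in order of dose. The count of the trend rested on single libraries: it was 0 without replicate 1, 2 or 3 of the 0.1% group or replicate 2, 3, 4 or 5 of the 10% group (2652 to 3503 genes at an unadjusted p below 0.05), 77 without replicate 2 or 3 and 121 without replicate 4 of the 1% group, 354 without replicate 1 of the 10% group and 940 without replicate 4 of the 0.1% group. Upper-quartile scaling gave 25 rising and 56 falling genes, and with the index of transcript ends as a covariate 0 were called (1613 at an unadjusted p below 0.05, and other tools were not run with it).

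The difference between 10% and 0.1% of the LC50 was set against that between 27 and 9 weeks to ask whether genes that differ with dose also differ with age. Across 19556 genes, which are not independent replicates, Pearson's r was 0.46 (permutation p = 0.0556 over 252 relabellings, with a smallest possible p of 0.00794). Among the other relabellings the highest absolute r was 0.542. Spearman's rho was 0.322 (permutation p = 0.159), so the correlation was not past the threshold. Both comparisons hold lower values for the 105 genes that fell over 8-fold at 27 weeks, among them LINGO3, MGAT3 and ANKRD52A. Without all genes that fell over 2-fold at 27 weeks, a choice made after seeing the data, r was 0.262 (permutation p = 0.143).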

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

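The tests of 5' parts of transcripts, of the share of neurons and of both explanations for the clock genes were chosen only after the result was seen. So were the rule that reads the gap test by its interval and the rule that sets the share of pairs against a comparison without the pattern. The telencephalon test was written before its result, but 5 of its 20 markers are in the neurogenesis list, whose result had been seen.

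The 105 genes that fell over 8-fold at 27 weeks, such as LINGO3 and MGAT3, were also lower at 10% against 0.1% of the LC50 (median -0.85), which shares no library with the comparison they were chosen from. A trend on annotated exon length shared by all genes is argued against as the cause. Removing each library's trend left the median log2 difference of these genes at -3.66 (quartiles -4.1 and -3.19, and -3.7 before). Their median exon length was 2845 bases against 2661 in the others. Exon length is that of the annotated models, so transcript length itself was not tested. An equal loss of all neurons as large as this fall is argued against too. The neuronal and synaptic list had a median of -0.29 (bootstrap 95% interval over genes, which are not independent, -0.42 to -0.15). A smaller loss, or loss of a type of neuron, was not tested. Loss of the 5' part of transcripts stays open: of 341 pairs of neighbouring gene models of the same symbol, the 5' model was the lower at 27 weeks in 67.4% (exact binomial p = 1.08e-10 across pairs, which are not independent), but in 83.9% at 10% against 1% and in 70.4% at 1% against 0.1%, where the 105 genes had a median of -0.06 and 0 were called, and of the 14 pairs that hold one of these genes it was the lower in 11 (exact binomial p = 0.0574), as in MLL4B (-4.09 against -0.12) but not in EIF2C1 (-0.26 against -4.36). A test written beforehand did not bear out its prediction of longer 3' gaps to the next gene: 43% of the 93 genes with both gaps had the longer one on the 3' side (exact 95% interval 32.8 to 53.7) against 45.5% of other genes (Fisher's exact p = 0.754), which does not decide it. The index of transcript ends was alike at 10% (-0.08) and at 27 weeks (-0.07), while the 105 genes stood at medians of -0.85 (against 0.1%) and -3.67. But 50 pairs lay over 2-fold apart between 27 and 9 weeks, and in 48 of these 50 the 5' model was the lower. Between 10% and 0.1% 2 pairs lay so far apart, both with the lower 5' model. Large gaps within a symbol thus nearly all went with a lower 5' model, which a median over all pairs does not show. The index therefore does not settle whether 5' loss gives both, and an effect of age, length of exposure or dose stays open beside RNA quality.

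In the clock list fixed beforehand, 20 of 31 genes had negative values at 1% against 0.1% of the LC50 (median -0.17). Both arms of the clock were drawn up after this result was seen, so their p-values describe it and are no independent support. All 14 tested genes of the output arm, NR1D1 among them, had negative values (median -0.67, 7 called). Its score differed by -0.76 (exact permutation p = 0.00794, n = 5 per group). The opposite arm, of ARNTL (0.3), CLOCK (0.23), NPAS2 (0) and ARNTL2 (-0.3) with 0 called, had a median of 0.12 (score difference 0.12, exact permutation p = 0.0238), which is consistent with tissue taken at another time of day, and the times are not given in the labels used here. The separate table of the 0.1% group stays open: within the other table the output arm differed between 10% and 1% by 0.28 (exact permutation p = 0.0873) and between 27 and 9 weeks by 0.39 (exact permutation p = 0.0317). An effect of the dose stays open as well and was not tested apart from these.

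EOMESA and TBR1B were higher at 27 weeks, and 1 deviating library as the whole cause is argued against, since the lowest fold left after leaving out any library was 0.8 of that with all (1.98 of 2.44 for EOMESA, and 2.04 of 2.55 for TBR1B, both on mean log2 CPM). Replicates 3 and 5 of the 1% group at 9 weeks together carry a large part of it, with EOMESA at 7.38 and 7.51 CPM against 34.2 to 79.7 in the other 3, and without the 3 libraries lowest for these markers, which include both, the edgeR values went from 1.77 to 1.1 for EOMESA and from 1.86 to 1.18 for TBR1B (adjusted p = 0.0405 and 0.0333). The 20 other telencephalon markers had a median of 0.5 between 27 and 9 weeks (16 positive, and 0.49 for the 15 outside the neurogenesis list). Of them 6 were called higher and 1 lower, LHX9 at -0.56 (edgeR adjusted p = 0.00044). Their median is what a larger share of telencephalon in the tissue taken would give, but not every one of these markers rose. The markers whose values had been seen before differed more (score difference 2.17, exact permutation p = 0.00794, n = 5 per group) than these (0.55, p = 0.0397), and hindbrain and spinal cord markers differed by 0.09 (p = 0.865). An effect of age or length of exposure on these neurons stays open.

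Other splits of the same libraries, 100 in each case with the real one included, were refitted for every count. For genes, under 5% of the splits drawn gave as many calls as the real one, which argues against a random split alone. It does not exclude that the groups line up with another structure of the libraries, since some other splits called more genes. As many were called in 1 split between 10% and 1% (1093, highest other 429) and in 1 between 27 and 9 weeks (5753, highest other 1100). As many were also called in 3 between 1% and 0.1% (233, highest other 585), in 2 between 10% and 0.1% (1087, highest other 1917) and in 2 assignments of the dose trend (223, highest other 426). The split with 1917 genes exchanges replicate 4 of the 0.1% group (index 0.024) and replicate 1 of the 10% group (index 0.049). These are the lowest index of transcript ends in the 0.1% group and the highest in the 10% group. Whether the calls of this split follow the index was not tested. The split with 585 puts replicates 1, 4 and 5 of the 0.1% group with replicates 3 and 4 of the 1% group. Within each group these libraries had the higher scores of the clock output arm, 0.77, 0.43 and 0.64 against 0.18 and 0.06 at 0.1%, and -0.08 and -0.1 against -0.48, -0.46 and -0.62 at 1%. This points to a structure of the samples along that score, looked up after the split was seen, whose cause was not tested. For the number of lists, chance cannot be excluded. Here 32 splits gave as many between 10% and 1% (12, highest other 16) and 73 between 27 and 9 weeks (7, highest other 16). In the other comparisons 53 gave as many between 1% and 0.1% (11, highest other 18) and 45 between 10% and 0.1% (12, highest other 18).

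Single libraries stood apart in 28 of 351 sets of 5 values tested (8%, over 148 genes and the library measures) by Dixon's ratio of the gap to the range, with a critical value of 0.71, and chance gives about 5% of sets, or 1 in 20. Replicate 3 of the 10% group accounts for 7 of them. In that library PRL was at 0.244 CPM against 101 to 461 in the other 4 (ratio 0.79) and LTBP1 at 3.22 against 5.74 to 6.07 (0.91). FAM135B was at 6.1 and below the other 4 (0.73), and MARCH5L at 5.42 against 7.65 to 8.27 (0.81). MYO6B was at 4.64 against 6.83 to 7.57 (0.79), SLC20A2 at 142 against 182 to 194 (0.8) and NFE2 at 251 against 226 to 227 (0.93). In replicate 2 of that group HER6 was at 27.7 CPM against 33.3 to 35.5 (0.74) and SOX3 at 24.8 against 27.9 to 29 (0.76), and in replicate 1 TAC1 was at 25.6 against 47.3 to 59.6 (0.73).

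In replicate 3 of the 1% group at 9 weeks ANKRD52A was at 5.28 CPM against 11.9 to 15.7 in the other 4 (ratio 0.74) and RYR3 (2 OF 2) at 3.4 against 13.5 to 19.3 (0.79). CACNG3B was at 6.93 against 8.77 to 9.23 (0.82) and ASNS at 29.2 against 18.8 to 20.8 (0.77). In replicate 4 DIABLO (2 OF 2) was at 0.243 against 1.88 to 2.69 (0.84), NEUROD4 at 1.55 against 2.24 to 2.45 (0.81) and CA6 (2 OF 2) at 7.96 against 4.53 to 4.79 (0.9). CORO1A was higher in replicate 1 than in the other 4 (0.72), and DCN was at 82.3 in replicate 5 against 56.6 to 62.9 (0.72). At 0.1% of the LC50, replicate 4 had NLGN2A at 67.8 CPM against 83.9 to 85.8 (0.9). It had 3.69% of its reads in its 10 most abundant genes against 3.08 to 3.23% (0.75). At 27 weeks, replicate 1 had GPR17 at 6.04 CPM against 4.48 to 4.81 (0.76) and PDGFRA at 49.2 against 30.8 to 33.4 (0.82). UNC119 was at 4.15 against 4.94 to 5.26 (0.74). TBR1B was at 39.4 in replicate 2 against 46.4 to 49.1 (0.74). NDUFS1 was at 340 in replicate 3 against 318 to 322 (0.83) and ZC3H12B at 0.24 in replicate 3 against 0.377 to 0.431 (0.76). The total count was at 29499193 reads in replicate 4 against 20953093 to 23028353 (0.76).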

How the results depend on the processing

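Chosen only after the data were seen were the index of transcript ends as a covariate, the removal of the exon length trend, leaving out the 3 libraries lowest for telencephalon markers, and leaving out genes that fell over 2-fold at 27 weeks. No paired analysis was possible because the titles give each library its own number and replicate numbers follow only the order of deposition. Of 174 results for named genes, 37 kept their direction and call under every alternative run and 0 reversed. Over all alternatives, 2947 values of named genes stayed on their side of the threshold and 670 lost the call in the same direction, and for lists the numbers were 670 and 125, with 3 reversed. The reversed medians were those of cytosolic ribosomal proteins with the index as a covariate (-0.02 at 10% against 1%, -0.04 at 10% against 0.1%) and of microglia markers at 1% against 0.1% without replicate 4 of the 0.1% group (0.03, the highest on leaving out 1 library, with -0.5 the lowest).

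Counts of called genes moved by over 1.5 times as follows. Fitting only the groups compared, with fewer libraries to estimate the spread, gave 183 at 10% against 1%, 17 at 1% against 0.1% and 281 at 10% against 0.1%. DESeq2 gave 1901, 554 and 1826 in these comparisons and 1147 for the dose trend. The RPKM values gave 97 at 10% against 1% and 2192 between 27 and 9 weeks. With the index as a covariate, which differs between the groups and so takes up part of their difference, the counts were 1 at 10% against 1%, 3 at 10% against 0.1%, 3623 between 27 and 9 weeks and 0 for the trend. Without the 3 libraries they were 571 at 10% against 1%, 46 at 1% against 0.1% and 52 for the trend, on fewer samples. The trend was also 81 with upper-quartile scaling, 113 with no filter and 1047 on linear dose. Between 27 and 9 weeks the other alternatives gave 4310 to 6468. For the other moves the cause was not tested.

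Counts of lists with an estimated correlation were 0, 0, 1 and 0 for 10% against 1%, 27 against 9 weeks, 1% against 0.1% and 10% against 0.1%, since camera then allows for members that vary together. Fry gave 6, 11 and 2 in the first 3. No filter gave 12 between 27 and 9 weeks, and the index as a covariate gave 6 at 10% against 1% and 3 between 27 and 9 weeks.

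Leaving out 1 library gave 175 to 1841 genes at 10% against 1%, 4635 to 5709 between 27 and 9 weeks, 66 to 356 at 1% against 0.1%, 209 to 1818 at 10% against 0.1% and 0 to 940 for the trend. The lists ranged over 9 to 14, 7 to 15, 9 to 13 and 10 to 14. The correlation of dose and age differences ranged from 0.396 to 0.494. It passed the threshold, with p from 0.0238 to 0.0476, without replicate 1 (0.429), 4 (0.494) or 5 (0.464) of the 0.1% group, replicate 2 of the 1% group (0.482), replicates 2 (0.466), 4 (0.452) or 5 (0.44) of the 10% group, or replicate 3 of the 27-week group (0.482). Not run were limma-trend on RPKM for comparisons with the 0.1% group, whose values are in a separate table, and the exon length trend for the dose trend and the correlation. At depths of 20193761 to 29499193 reads, the simulation of 27 against 9 weeks recovered 38 of 67 genes changed 1.5-fold. It held 200 changed genes, while the real comparison called 5753, with a median absolute log2 fold change of 0.43 among them. The adjustment was therefore less strict in the real comparison, and the simulation does not give its detection limit. Differences that were not called may still be present.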

Other observations

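All lists in this part were fixed before the data were examined, and the tests on pairs of gene models were chosen only after the result was seen. The collagens COL12A1 and COL6A3 were lower at 27 weeks, while the list of vascular, meningeal and matrix genes did not pass its test (median -0.24, adjusted p = 0.111). Of its 50 genes 13 were lower and 5 higher, or 13 and 7 adjusted over the list alone, with COL12A1 at -3.08 ± 0.25 and COL6A3 at -2.86 ± 0.23 (SE, edgeR adjusted p = 1.04e-08 and 6.8e-09). Both were also lower at 10% against 0.1% of the LC50 (-0.86 ± 0.21 and -0.95 ± 0.2, adjusted p = 0.0269 and 0.014). At 10% against 1% the endothelial cadherin CDH5 changed by -0.33 ± 0.07 and the proteoglycan DCN by -0.4 ± 0.1 (adjusted p = 0.0171 and 0.0255). The list did not pass its test there either (median -0.02, adjusted p = 0.334). It had 0 of 50 genes higher and 4 lower, or 0 and 5 adjusted over the list alone. Of 21 radial glia and astrocyte genes 3 were higher and 4 lower at 27 weeks, also 3 and 4 adjusted over the list alone (median -0.06, adjusted p = 0.809). There SLC1A2B was at -1.11 ± 0.1 and NOTCH3 at -0.52 ± 0.08 (adjusted p = 4.29e-08 and 7.27e-05). Of 42 genes of monoaminergic and cholinergic neurons 5 were higher and 2 lower, or 4 and 2 adjusted over the list alone (median -0.07, adjusted p = 0.963). There the dopamine receptor DRD1 was at -1.63 ± 0.1 and PARK7, a redox-sensitive chaperone, at 0.28 ± 0.06 (adjusted p = 2.3e-10 and 0.000763). At 10% against 1%, TH, the rate-limiting enzyme of dopamine synthesis, was higher by 0.63 ± 0.14 and DRD1 lower at -0.5 ± 0.1 (adjusted p = 0.0177 and 0.0126). TH stood at 7.63 to 15.5 CPM per library at 0.1%, 8.15 to 10.6 at 1% and 11.6 to 16 at 10%. The list of these neurons did not pass at 10% against 1% (2 of 42 higher and 1 lower, median 0.04, adjusted p = 0.396).

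Stress and metabolic genes differed singly between 27 and 9 weeks. In the antioxidant list 6 of 29 genes were higher and 0 lower, also 6 adjusted over the list alone (median 0.15, adjusted p = 0.0604). There the ferritin FTH1A was at 0.35 ± 0.05 and SQSTM1, an autophagy receptor that overlaps another gene, at 0.49 ± 0.13 (adjusted p = 1.4e-05 and 0.0078). In the integrated stress response 1 of 24 was higher and 5 lower, also 1 and 5 adjusted over the list alone (median 0.03, adjusted p = 0.963). There VLDLR was at 0.38 ± 0.05 and asparagine synthetase, ASNS, at -0.46 ± 0.09 (adjusted p = 2.68e-06 and 0.000468). Of 26 glycolysis and lactate genes 3 were lower, also 3 adjusted over the list alone (median 0.07, mean -0.06, adjusted p = 0.975). There the lactate transporter SLC16A3 was at -2.86 ± 0.25 and hexokinase HK2 at -0.44 ± 0.11 (adjusted p = 2.43e-08 and 0.00422). In xenobiotic metabolism 1 of 16 was higher and 2 lower, also 1 and 2 adjusted over the list alone (median 0.12, adjusted p = 0.953). There ARNT was at -1.14 ± 0.13 and TIPARP, a target of the aryl hydrocarbon receptor, at 0.75 ± 0.12 (adjusted p = 6.69e-07 and 9.55e-05). Immediate early genes had 5 of 31 higher, also 5 adjusted over the list alone (median 0.1, adjusted p = 0.0643). There NR4A3 was at 0.63 ± 0.13 and DUSP6 at 0.62 ± 0.15 (adjusted p = 0.00115 and 0.00361). NR4A3 stood at 19.5 to 24.2 CPM per library at 1% and 9 weeks and at 29.7 to 42.9 at 27 weeks. At 0.1% of the LC50 and 9 weeks it stood higher, at 40.2 to 57.6. In DUSP6 and TIPARP the 27-week libraries overlapped those at 0.1%. Other respiratory chain genes had 3 of 29 higher and 1 lower, or 3 and 0 adjusted over the list alone (median 0.02, adjusted p = 0.472). There COX6B1 was at 0.44 ± 0.1 and UQCRC2A at 0.22 ± 0.06 (adjusted p = 0.00212 and 0.00629).

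Lists of tissue next to the brain held few called genes at 27 weeks. Retina and pineal genes had 4 of 30 higher and 1 lower, or 3 and 1 adjusted over the list alone (median 0.01, adjusted p = 0.463), of which UNC119 and UNC119B, at 0.67 ± 0.16 and 0.27 ± 0.07 (adjusted p = 0.00301 and 0.00414), overlap other genes. Muscle genes had 6 of 38 lower, or 5 adjusted over the list alone (median 0.08, mean -0.07, adjusted p = 0.939), including NEB, the giant muscle protein nebulin, whose 2 gene models changed by -1.5 ± 0.12 and -3.98 ± 0.72 (adjusted p = 6.74e-09 and 0.000273). At 10% against 1% they changed by -0.62 ± 0.12 and -3.31 ± 0.67 (adjusted p = 0.0106 and 0.0134). The NEB model with the larger changes had a low level, 0.134 to 1.97 CPM per library at 1% and 9 weeks. It was at 0.0336 to 0.144 at 27 weeks and 0 to 0.344 at 10%, so the groups overlapped in both comparisons. Blood cell genes (1 of 12 lower, median -0.12, adjusted p = 0.796), lymphocytes and granulocytes (1 of 12 lower, median 0.17, mean -0.07, adjusted p = 0.975), antigen presentation (1 of 21 lower, median 0.29, adjusted p = 0.472), lens crystallins (0 of 6, median -0.08, adjusted p = 0.963) and proteasome genes (1 of 40 higher and 1 lower, median -0.01, adjusted p = 0.963) did not pass either. Of mitochondrially encoded proteins 2 genes matched and 0 passed the filter, so that list was not tested.

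Pairs of gene models with the same symbol gave the 5' model as the lower in 87.4% of 341 pairs at 10% against 0.1%. Between 27 and 9 weeks 50 pairs lay over 2-fold apart and in 48 of them the 5' model was the lower, while at 10% against 1% there were 0 such pairs. Examples between 27 and 9 weeks are HERC2 (-3.51 in the 5' model and -0.03 in the 3' model), INSRB, the insulin receptor (-3.72 and -0.26), and the netrin receptor DCC (-3.74 and -0.59), while CPNE5 (-2.65 and -3.11) and PCDHAC2 (1 OF 2) (-1.03 and -3.28) went the other way.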
